A study of Homo sapiens with 3 samples.

How the data were processed

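The series held 3 arrays of 1 oligonucleotide array type, with 1 culture per condition. Per the labels' protocols 200 ng of total RNA was labelled with biotin for each array, and the growth medium held 10% serum. Per the submitters' processing notes the intensity values as deposited were made with MAS5. Its version and settings were not given in the sources used here. The values were checked to be on a linear scale, and after 2% was left out at either end each array had a mean of 1000, as global scaling to that target would leave. The scaling is read from the values and is stated in no source used here. Detection calls and raw image files were not used here.

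Of 54675 probe sets, 62 controls were set aside for quality measures. Of the other 54613, 41091 were listed with 1 gene, 1801 with several and 11721 with none in the platform table. Gene names were checked by Entrez ID against the RefSeq gene table of the human assembly GRCh38.p14, which matched 41037 probe sets and changed 0 symbols. No coordinates were used. The 41091 probe sets gave 19775 genes, 10523 of them with several probe sets. Each gene was represented by its brightest probe set over the arrays.

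Signals below a floor were raised to it before log2 ratios were taken. The floor was the median of all values on the 3 arrays together, 149.8. A gene entered a comparison if its probe set was above the floor on at least 1 of its arrays. Where the lower array was at the floor the ratio is a lower bound, written as "at least". A gene was called higher or lower at 2-fold. With 1 array per condition no test and no error across cultures could be computed, so no p-values are given. The spread of log2 ratios between probe sets of the same gene, over 5180 genes, served as the technical SD. It was used to simulate 100 sets of unchanged arrays, with dim, middle and bright genes drawn apart. The 2-fold calls on these sets are given beside the observed counts. For genes that turned back, 100 further sets kept the undifferentiated array as measured and put both PMA arrays at their mean level. In both simulations a gene's class came from its mean over all 3 arrays, and the SD from genes above the floor on all 3. Genes dimmer on the arrays compared could thus get too small an SD, which would make the simulated counts too low.

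The 42 gene lists were written by hand from general knowledge, before the data were examined. They cover macrophage, progenitor and granule, cell cycle, immune, lysosome, lipid, matrix, adhesion, cytoskeleton, signalling, stress, metabolism and cell type genes. A list's median log2 ratio was set against 10000 random lists with the same number of genes drawn from the same 20 bins of mean expression. Above or below random lists means outside the central 95% of them. This describes where a list stands among genes on these arrays and is no test between conditions. Of the 42 lists 20 were above and 9 below at PMA 3 days over undifferentiated, 21 and 10 at PMA 8 days over undifferentiated, and 8 and 12 at PMA 8 days over PMA 3 days. Lists share members, so these counts are not independent.

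The genes named in the text follow a rule fixed before the data were examined. Per comparison and direction it takes the 10 largest ratios measured on both arrays with every informative probe set of the gene going the same way, and the 5 brightest genes with the other array at the floor. It adds up to 4 members of a list past 2-fold per comparison, and 5 genes per direction that turned back between PMA 3 and 8 days. A gene among the largest increases that the rule takes is not reported here. Genes in the closing section that fall outside it are marked there. The comparisons, floor, threshold and alternatives were also set before the data were examined, apart from the scaling to poly-A controls, which was added after these controls were seen to be higher on the PMA 3 days array.

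The steps were tested on simulated data. Arrays with 200 changed genes were built from the measured spread, 50 at each of 4 sizes. The changed genes were drawn only from those with a mean level more than 2-fold above the floor. Recovery of genes nearer the floor was not tested. A true 2-fold change was called in 40% (PMA 3 days over undifferentiated), 40% (PMA 8 days over undifferentiated) and 46% (PMA 8 days over PMA 3 days) of the genes, a 3-fold change in 98%, 96% and 100%, and 4-fold and 8-fold changes in 100% of them. Of 200 lists of 30 genes drawn at random from these simulated arrays, 5.5%, 7.5% and 3% fell outside the range of random lists. A low share follows from the construction, and the changed genes were not left out. How much medians of lists of co-regulated genes vary was not tested. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.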

Results

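THP-1 is an established human monocytic leukemia cell line. Its cells grow as undifferentiated monocyte precursors and turn into adherent, macrophage-like cells when given phorbol myristate acetate (PMA), a drug that activates protein kinase C. Total RNA was measured on 1 biotin-labelled, 1-colour oligonucleotide array from each of 3 cultures: undifferentiated cells, cells labelled PMA 3 days and cells labelled PMA 8 days. By the labels' protocols both PMA cultures began in 200 nM PMA. The PMA 3 days culture had PMA for 24 h and then 3 days without it, which adds up to 4 days, and the PMA 8 days culture had PMA for 72 h and then 5 days without it. A switch to medium with 2% serum came 16 h before RNA was taken; the protocol does not say whether it included the undifferentiated cells. Time in culture, time in PMA and time since PMA therefore differed together between the PMA cultures. There were no replicates: every value below is from 1 array, no test between conditions was possible, and "higher" or "lower" means a difference of at least 2-fold between 2 arrays unless a value is given.

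Quality was measured on each array. Each had a trimmed mean signal of 1000, and 51.4% (undifferentiated), 48.5% (PMA 3 days) and 50.1% (PMA 8 days) of the probe sets lay above the floor of 149.8 signal units. Across probe sets the log2 signals of the PMA arrays correlated with each other at r = 0.982, and with the undifferentiated array at r = 0.900 (PMA 3 days) and r = 0.908 (PMA 8 days). The ratio of 3' to 5' signal, which grows as RNA degrades, was 1.37, 1.36 and 1.49 for actin and 1.16, 1.10 and 1.12 for GAPDH in the order undifferentiated, PMA 3 days, PMA 8 days. After quantile normalization these were 1.32, 1.42 and 1.55 for actin and 1.10, 1.14 and 1.14 for GAPDH. The poly-A labelling controls had a median log2 ratio of 0.31 in PMA 3 days over undifferentiated and -0.29 in PMA 8 days over PMA 3 days. Apart from the spread of the control probe sets, the only error that could be estimated was the disagreement of probe sets for the same gene. It gave a technical SD of a log2 ratio of 0.397 for PMA 3 days over undifferentiated, 0.402 for PMA 8 days over undifferentiated and 0.245 for PMA 8 days over PMA 3 days. This SD covers neither culture nor labelling differences. It can also hold real differences between transcripts of a gene read by different probe sets, so it need not be purely technical.

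The first comparison asked which transcripts differed between PMA 3 days and undifferentiated cells. Genes of macrophages, the extracellular matrix, lysosomes and the interferon response were higher, and genes of myeloid progenitors, neutrophil-type granules, the cell cycle and metallothioneins were lower. CD163, the haemoglobin scavenger receptor of macrophages, went from 218 to 26654 signal units, 122-fold. ELANE, the neutrophil elastase made by granulocyte precursors, went from 32064 to 156, 206-fold lower. Its PMA 3 days signal lay just above the floor of 149.8, so the size of this fold depends on the floor. The same holds for CD163 and for several other large folds named below at either PMA time. Undifferentiated signals were 157 for FERMT2 and 166 for ABCC3, for example, under the 60th percentile floor of 261. Of 13319 genes above the floor on at least 1 of the arrays, 1374 were higher and 1422 lower, and 504 and 275 of them by at least 4-fold. Simulated unchanged arrays with the technical spread alone gave a mean of 202 genes past 2-fold in both directions together (lowest 169, highest 234). Higher genes made up 49.1% of the calls, and 28.7% when the arrays were scaled to the poly-A control transcripts instead. The median log2 ratio of all genes was -0.12, and -0.39 and 0.00 under poly-A control scaling and centring, so that the places of lists among random lists are relative to other genes. The balance of directions thus rests on the scaling.

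Among the measured genes with the largest increase were, after CD163, FN1 (fibronectin, 105-fold), TDO2 (a tryptophan-degrading enzyme, 74.7-fold), S100B (a calcium-binding protein, 74.7-fold), ADAMDEC1 (a secreted metalloprotease, 71.9-fold), ABCC3 (an organic anion transporter, 64.2-fold), FERMT2 (kindlin-2, an integrin activator, 60.7-fold), TFPI (an inhibitor of coagulation, 47.0-fold) and PHLDA1 (42.3-fold). Some genes were below the floor in undifferentiated cells, so that their change is a lower bound. The brightest of these were RGS1, a regulator of G-protein signalling (at least 177-fold), the collagen gene COL6A3 (at least 93.0-fold), the myosin light chain kinase MYLK (at least 78.6-fold), the guanylate-binding protein GBP1 (at least 62.0-fold) and the macrophage elastase MMP12 (at least 59.5-fold). In the other direction, ELANE was followed by AZU1 (azurocidin of granules, 53.4-fold lower), GPR160 (51.3-fold), DHRS9 (51.1-fold), MYB (a transcription factor of progenitors, 46.9-fold), CCR2 (the monocyte chemokine receptor, 44.6-fold), CACNA2D3 (43.1-fold), CTSG (the granule protease cathepsin G, 43.1-fold), PHACTR3 (29.3-fold) and RGS18 (26.5-fold). The brightest genes that ended below the floor were MS4A3 (at least 46.3-fold lower), GFI1 (at least 41.4-fold), PRTN3 (granule proteinase, at least 17.0-fold), SERPINB10 (at least 13.7-fold) and ANKRD18A (at least 12.8-fold).

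**Figure D1:**
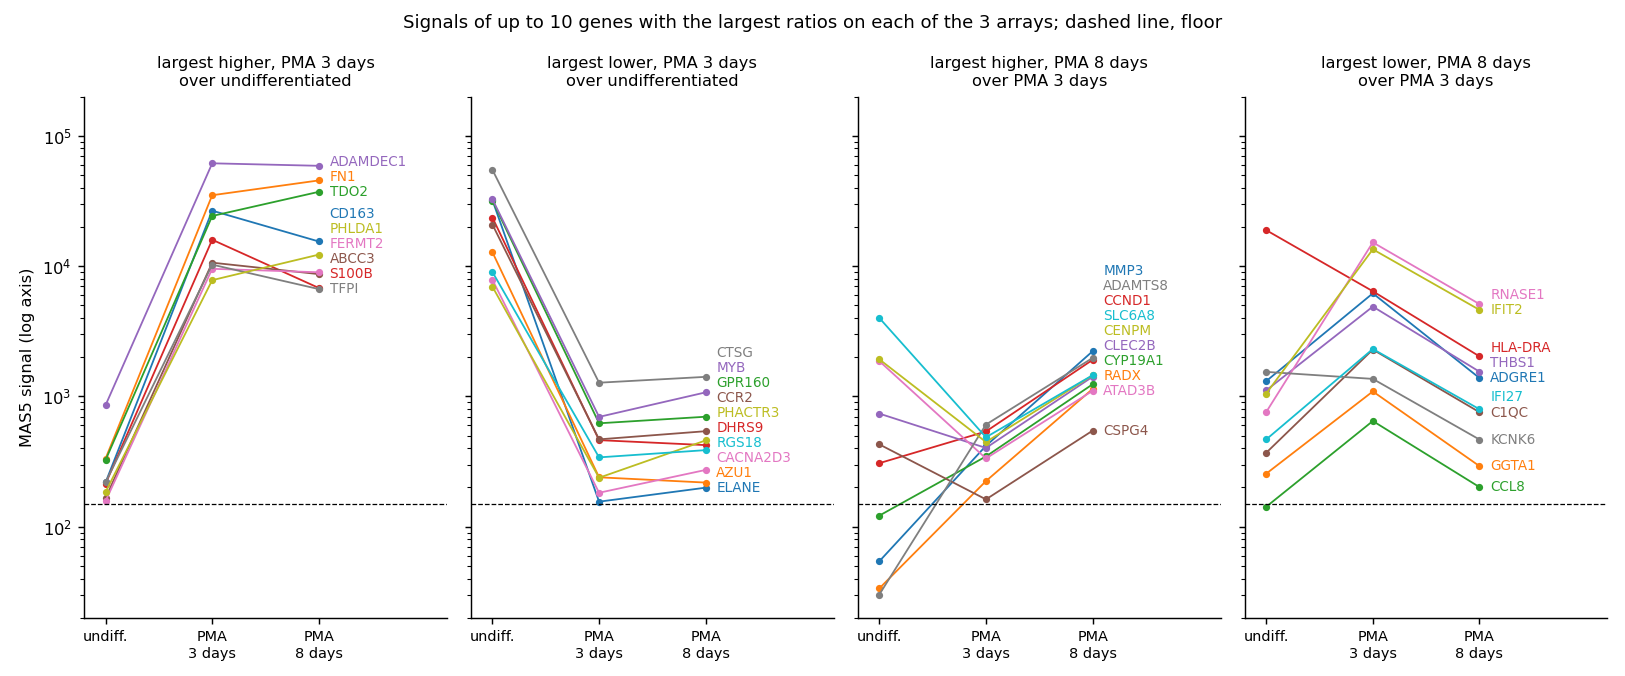
MAS5 signal (log axis) of single genes on the undifferentiated, PMA 3 days and PMA 8 days arrays, 1 line per gene and 1 point per array; panels hold up to 10 genes with the largest ratios in each direction, and the dashed line marks the floor of 149.8. CD163 went from 218 to 26654 and 15456, and ELANE from 32064 to 156 and 199, while RNASE1, IFIT2 and ADGRE1 peaked on the PMA 3 days array.

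Macrophage markers were higher as a group: 22 of 26 measured members, with 1 lower, and a median log2 ratio of 2.23. Besides CD163 these included the endotoxin co-receptor CD14 (40.2-fold), the scavenger receptor MSR1 (at least 26.3-fold) and GPNMB (9.90-fold). Lysosomal genes were higher in 26 of 45 cases and lower in none (median 1.23), among them the cathepsin genes CTSK (22.1-fold), CTSL (9.67-fold) and CTSD (8.63-fold) and MITF, a transcription factor of lysosomal genes (11.2-fold). Matrix genes and matrix proteases were higher in 27 of 35 cases and lower in 2 (median 1.92), led by FN1, ADAMDEC1, MMP12 and MMP8 (at least 46.4-fold). Integrins and adhesion genes were higher in 16 of 32 and lower in 2 (median 0.99), with ITGB5 at 15.9-fold, ITGB8 at no less than 10.1-fold and ITGB7 at 6.65-fold higher, and ITGA7 at least 6.12-fold lower. Lipid-handling genes were higher in 16 of 35 and lower in 5 (median 0.72): the fatty acid carrier FABP4 was 41.1-fold and APOE 6.91-fold higher, and MYLIP, which marks the LDL receptor for degradation, was 13.4-fold lower. Cytoskeletal genes were higher in 7 of 38 and lower in 2, with a median of 0.19 (-0.11 under poly-A control scaling, where that of all genes went from -0.12 to -0.39); TUBB2A (7.22-fold) and TPM2 (7.09-fold) led. All 6 medians lay above the range of matched random lists, which holds the central 95% of 10000 of them.

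The progenitor and granule list was lower in 16 of 20 measured members and higher in none, with a median log2 ratio of -3.29, led by ELANE, AZU1, MYB and MS4A3. Cell cycle genes were lower too. In the G2/M list 34 of 40 were lower and none higher (median -1.54); KIF20A, a kinesin of late mitosis, was 6.37-fold, the centromere kinesin CENPE 4.37-fold and ASPM 4.18-fold lower. In the G1/S list 18 of 39 were lower and none higher (median -0.94), among them the replication genes MCM7 (4.16-fold), CDC45 (4.13-fold) and CDT1 (2.95-fold). Of the cell cycle inhibitors, 5 of 15 were higher and 1 lower (median 0.01, inside the random range), and the cyclin-dependent kinase inhibitors CDKN1C (5.21-fold) and CDKN1A (4.34-fold) were the largest. Metallothionein genes, which bind zinc and copper and are so alike that their probe sets can share signal, were lower in 7 of 8 cases (median -2.20), with MT1E at 14.0-fold. Ribosome biogenesis genes had a median of -0.68 with 4 of 30 past 2-fold, all lower, such as EMG1 (2.97-fold) and fibrillarin, FBL (2.74-fold). Cholesterol synthesis genes had a median of -0.58 with 2 of 18 lower, SREBF2 (2.59-fold) and TM7SF2 (2.26-fold), and none higher. Apart from the inhibitors, these medians lay below the range of matched random lists.

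Immune genes were higher in several lists. Of interferon-stimulated genes 25 of 35 were higher and none lower (median 1.64), with IFIT1 at a log2 ratio of 3.90, IFIT2 at 12.8-fold and IFI44 at 10.0-fold besides GBP1. Cytokines and chemokines were higher in 16 of 29 cases and lower in 1 (median 1.71): the platelet chemokine PPBP by at least 21.7-fold, CXCL10 by 16.3-fold, CXCL2 by 11.5-fold and CXCL3 by at least 10.2-fold. Targets and regulators of NF-kB were higher in 6 of 22 (median 0.70), with BCL2A1 at no less than 12.7-fold and SOD2 at 3.99-fold. Complement genes were higher in 11 of 20 and lower in 3 (median 1.05); the receptors C5AR1 (at least 34.1-fold) and C3AR1 (23.1-fold) were higher and the protease CFD 9.65-fold lower. Fc and pattern receptors were higher in 15 of 37 and lower in 4 (median 0.61), with the endotoxin co-receptor LY96 at 19.0-fold and CLEC4A at 13.3-fold higher and IRAK3, a brake on toll-like receptor signalling, 11.5-fold lower. Chemokine and cytokine receptors went both ways, 12 of 35 higher and 9 lower (median 0.52, but -0.59 over the second-brightest probe sets of only 19 members): the decoy receptor IL1R2 (at least 58.7-fold) and the formyl peptide receptor FPR3 (at least 48.1-fold) were higher and CCR2 lower. MHC class I and antigen processing genes were higher in 6 of 18 (median 0.67), led by the peptide transporter TAP1 (4.06-fold). By the brightest probe sets these medians stood above matched random lists. MHC class II genes had a median of -0.24, inside the random range, with 5 of 12 lower, such as HLA-DQA1 (5.14-fold) and HLA-DQB1 (3.67-fold). Lists of alternative (M2) and classical (M1) macrophage activation were both above random lists: 13 of 24 higher and 1 lower for the first (median 1.31), and 7 of 19 higher and 2 lower for the second (median 0.45). The lists share members with those above, among them CD163, FN1 and MSR1 in the first and GBP1 and CXCL10 in the second.

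Regulators of the myeloid lineage went both ways, 9 of 34 higher and 13 lower (median -0.40, below random lists): MYB, GFI1 and IRF8 (13.9-fold) were lower, and BHLHE41 was at least 29.5-fold higher. Immediate early genes of the AP-1 and EGR pathways were higher in 12 of 25 and lower in none (median 0.67, above random lists), with PHLDA1, the phosphatase DUSP1 (20.3-fold) and MAFF (7.25-fold) in front. The list named for protein kinase C and phorbol receptors gave 3 higher and 5 lower of 22 (median -0.47, inside the random range). Whether each member binds PMA was not checked. RASGRP2 was 13.7-fold lower and RASGRP3 4.90-fold higher, and PRKCA was 2.75-fold lower by its brightest probe set but not by the next (log2 ratio 0.02). In the antioxidant and iron list, 7 of 26 were higher and 2 lower (median 0.15, inside the range), with heme oxygenase HMOX1 at 42.2-fold and GCLC at 8.72-fold higher and the iron exporter SLC40A1 8.19-fold lower. Eicosanoid genes were higher in 6 of 19 and lower in 3 (median 0.33, above random lists), with ALOX5 at 7.49-fold and TBXAS1 at 6.36-fold. Unfolded protein response genes had a median of 0.35, above random lists, with DNAJB9 2.77-fold higher and EDEM1 2.53-fold lower. Apoptosis regulators had a median of 0.25, above random lists (-0.05 under poly-A control scaling, which moved all genes down alike), with 4 of 25 higher and 3 lower. BIK was 5.54-fold lower, and BCL2 at least 24.5-fold lower by its brightest probe set but not by the next (log2 ratio 0.11). The p53 target list (6 of 18 higher, 3 lower, median 0.29), hypoxia (5 of 22 higher, 3 lower, 0.15), glycolysis (2 of 24 higher, 2 lower, -0.17), NADPH oxidase (1 of 8 higher, 0.23) and oxidative phosphorylation (0 of 27 past 2-fold, -0.07) had medians inside the random range.

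Markers of cell types were followed as well. Monocyte markers had a median of -0.97 with 7 of 16 lower and 2 higher: CCR2 and CLEC12A (at least 6.84-fold) were lower while CD14 and LILRB2 (4.80-fold) were higher. Granulocyte markers had a median of -1.44 (4 of 7 lower, 1 higher), below random lists like the monocyte markers; the gene that was higher was MMP8. Osteoclast markers, which share genes with the lysosome, matrix and adhesion lists, were higher in 8 of 11 cases and lower in 1 (median 1.25, above random lists), with MMP9 at 37.9-fold and CTSK at 22.1-fold higher and CA2 4.36-fold lower. Dendritic markers were higher in 5 of 15 and lower in 4 (median -0.07), with CD1E at 7.19-fold and the lipid-presenting CD1A at 4.24-fold. Lymphoid markers (2 of 10 higher, 1 lower, median 0.07), erythroid and megakaryocyte markers (2 of 8 higher, 1 lower, -0.07) and the fibroblast, epithelial and endothelial markers (3 of 9 higher, 0.08) had medians inside the random range. GNLY (at least 8.65-fold), PPBP and FAP (at least 14.5-fold) were the largest in these last lists, in that order; COL1A1 was 5.03-fold higher by its brightest probe set and not by the median of its probe sets (log2 ratio -0.03).

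The second comparison asked the same of PMA 8 days. Of 13582 genes above the floor, 1320 were higher and 1140 lower than in undifferentiated cells, 446 and 234 of them by at least 4-fold. Unchanged arrays gave a mean of 206 genes past 2-fold in both directions together (161 to 246). Among the genes with the largest increase were FN1 (137-fold, to 45488 signal units), TDO2 (115-fold), CD163 (70.8-fold), ADAMDEC1 (68.8-fold), PHLDA1 (66.5-fold), FERMT2 (57.0-fold), ABCC3 (52.4-fold), the gelatinase MMP9 (41.3-fold) and NT5E, the ectoenzyme that makes adenosine (40.6-fold). RGS1 (at least 247-fold), COL6A3 (at least 117-fold) and MMP12 (at least 69.5-fold) were again among the brightest that started below the floor. ELANE (161-fold), AZU1 (58.7-fold), DHRS9 (55.8-fold), GPR160 (45.6-fold), CTSG (38.8-fold), CCR2 (38.6-fold), MYB (30.4-fold), MS4A3 (from 6936 to 231 signal units), CACNA2D3 (28.8-fold) and MS4A6A (28.4-fold) were the lowest among genes measured on both arrays. PRTN3, SERPINB10, CNTN4 (at least 10.5-fold), NEGR1 (at least 10.5-fold) and the progenitor cytokine receptor FLT3 (at least 9.86-fold) were the brightest that ended below the floor.

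Most lists stood on the same side of the random lists as at PMA 3 days. Macrophage markers were higher in 20 of 27 and lower in 1 (median 2.04), lysosomal genes in 27 of 45 (1.16), matrix genes in 26 of 35 with 2 lower (2.15), adhesion genes in 17 of 32 with 2 lower (1.18), lipid-handling genes in 15 of 36 with 5 lower (0.50) and cytoskeletal genes in 9 of 38 (0.48). Progenitor and granule genes were lower in 16 of 20 (-3.31), and metallothioneins in 6 of 8 (-1.61). Cytokines and chemokines were higher in 15 of 30 and lower in 3 (0.99), NF-kB targets in 7 of 22 with 1 lower (0.35), complement genes in 6 of 19 with 2 lower (0.68), MHC class I genes in 5 of 18 (0.57), M2 genes in 12 of 24 with 1 lower (0.96), M1 genes in 6 of 21 with 2 lower (0.32), immediate early genes in 11 of 26 (0.57) and osteoclast markers in 7 of 11 with 1 lower (1.17). Apoptosis regulators were above random lists again (0.29, 4 of 25 higher, 3 lower). Antioxidant and iron genes (0.36, 7 of 27 higher, 2 lower) and p53 targets (0.35, 6 of 18 higher, 2 lower) were above them at this time only. Over the second-brightest probe sets, held by only 7 of the p53 targets, the median was -0.27. Fc and pattern receptors (0.23, 12 of 37 higher, 3 lower) and chemokine and cytokine receptors (0.23, 11 of 35 higher, 9 lower) were above random lists by the brightest probe sets. Their medians over the second-brightest, of only 17 and 18 members, were -0.09 and -0.42. These medians are over smaller sets of genes, so they do not compare probe sets of the same members. The fibroblast, epithelial and endothelial list was above random lists (0.40, 3 of 10 higher); FAP (at least 22.8-fold) and PDGFRA (at least 6.41-fold) were higher, and COL1A1 only by its brightest probe set (log2 ratio -0.08 by the next and by the median of its probe sets).

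The cell cycle was nearer to undifferentiated cells than at PMA 3 days. In the G2/M list 6 of 40 were lower (median -0.60), with PLK1 at 3.56-fold and KIF20A at 3.10-fold, and in the G1/S list 5 of 39 (median -0.50), with CDT1 at 3.47-fold; both medians were below random lists. MHC class II genes were lower in 7 of 11 and higher in 1 (median -1.45): HLA-DQA1 by at least 9.43-fold, HLA-DRA by 9.31-fold and HLA-DQB1 by 6.14-fold. Monocyte markers were lower in 10 of 16 and higher in 2 (median -1.63), with the proteoglycan VCAN at 10.4-fold. Interferon-stimulated genes were higher in 17 of 35 and lower in 1 (median 0.91), GBP1 by at least 54.3-fold and IFIT1 by 7.83-fold. Granulocyte markers (-1.43, 5 of 8 lower, 2 higher), cholesterol synthesis (-0.48, 1 of 18 lower, 1 higher), ribosome biogenesis (-0.40, 2 of 30 lower) and protein kinase C and phorbol receptors (-0.52, 4 of 22 lower, 3 higher) were below random lists. Inside the random range were myeloid transcription factors (-0.29, 8 of 34 higher, 13 lower), eicosanoid genes (0.20, 6 of 20 higher, 3 lower), unfolded protein response (0.23, 1 of 26 lower), cell cycle inhibitors (0.14, 4 of 15 higher, 1 lower), NADPH oxidase (-0.16, 1 of 8 higher), glycolysis (0.05, 3 of 23 higher, 2 lower), oxidative phosphorylation (0.08, 0 of 27 past 2-fold), hypoxia (0.05, 6 of 22 higher, 1 lower), dendritic (-0.01, 5 of 15 higher, 4 lower), lymphoid (-0.12, 1 of 8 higher) and erythroid and megakaryocyte markers (0.08, 1 of 8 higher, 1 lower).

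**Figure D2:**
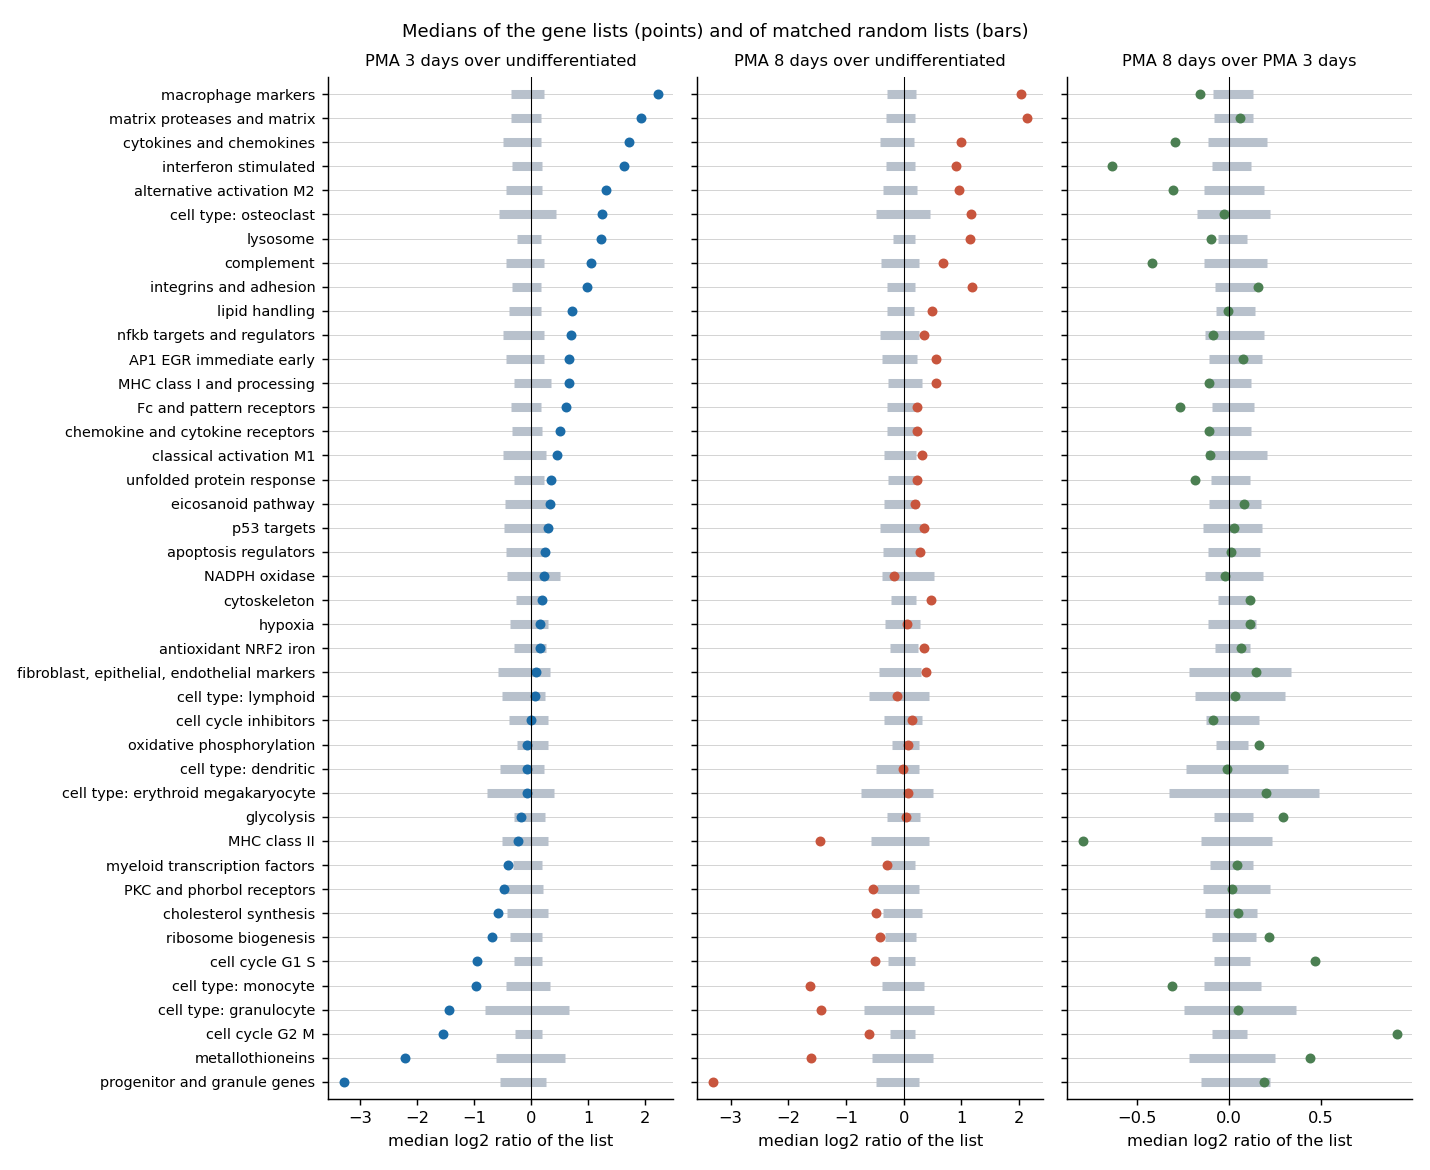
Median log2 ratio of each of the 42 gene lists (points) in the 3 comparisons, with the central 95% of 10000 matched random lists (grey bars); the x axis of the last panel is finer. Macrophage markers lie at 2.23 and 2.04 and progenitor and granule genes at -3.29 and -3.31 against undifferentiated cells, and the G2/M list lies at 0.91 in PMA 8 days over PMA 3 days.

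The changes at the PMA times were largely in the same genes. Of 13116 genes measured in both comparisons, 1088 were higher and 903 lower at both times and 0 went in opposite directions. Independent lists of these sizes would share 260 in the same direction, and unchanged arrays set against the same undifferentiated array shared a mean of 32.3 (20 to 44). The log2 ratios correlated across genes at r = 0.931 (Spearman rho 0.884), where unchanged arrays gave r = 0.504 (rho 0.483) from the shared array alone. Their covariance was 0.929 against 0.0776 for unchanged arrays, a difference of 0.851. Genes are not replicates, and part of the overlap may come from the shared undifferentiated array, which could not be split.

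**Figure D3:**
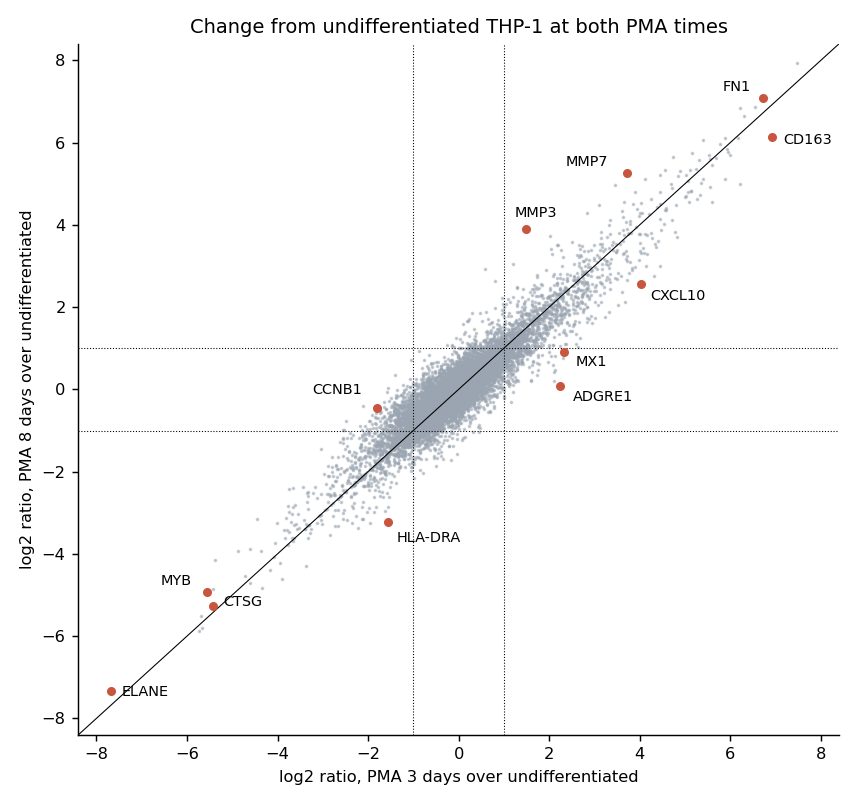
Log2 ratio over undifferentiated cells at PMA 3 days (x) and PMA 8 days (y), 1 point per gene above the floor in both comparisons; dotted lines mark 2-fold, the diagonal marks equal ratios, and red points are labelled genes. The points run along the diagonal (r = 0.931); MMP3 and CCNB1 lie above it, and ADGRE1, MX1 and HLA-DRA below it.

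The third comparison set PMA 8 days against PMA 3 days. Far fewer genes differed. The medians of the cell cycle lists lay above random lists, and those of interferon-stimulated, complement, MHC class II and monocyte genes below them, while most members of each list stayed within 2-fold. Of 13066 genes above the floor, 179 were higher and 122 lower, with 2 and 1 past 4-fold: the matrix protease MMP3 (5.32-fold, from 418 to 2221 signal units) and RADX (5.09-fold, from 224 to 1140) were higher, and the macrophage receptor ADGRE1 (4.47-fold) was lower. Unchanged arrays gave a mean of 10 calls (4 to 17), which may be too low for genes dim on the PMA arrays alone. Of the 301 genes 216 were dim by their mean over the 3 arrays. The counts changed with the floor and with the scaling: higher genes made up 59.5% of the calls and 92.2% under poly-A control scaling. The other large increases were in CYP19A1, the aromatase that makes estrogens (3.58-fold), the G1 cyclin CCND1 (3.55-fold), CLEC2B (3.52-fold), CSPG4 (3.37-fold), ATAD3B (3.30-fold), ADAMTS8 (3.25-fold), the centromere gene CENPM (3.24-fold) and the creatine transporter SLC6A8 (2.99-fold). GGTA1 (3.74-fold), the chemokine CCL8 (3.22-fold), HLA-DRA (3.16-fold), thrombospondin THBS1 (3.16-fold), the complement gene C1QC (3.03-fold), RNASE1 (2.98-fold), the potassium channel KCNK6 (2.92-fold), IFIT2 (2.92-fold) and IFI27 (2.90-fold) were lower. Those that were below the floor on the other array were dimmer: ANHX (at least 3.53-fold), ELK2AP, TMEM120B, CLDN19 and LRP3 reached 448 to 528 signal units at PMA 8 days, and PEMT (at least 2.74-fold), ADIRF-AS1, ZNF696, STAP1 and TNFRSF14-AS1 had 367 to 410.3 at PMA 3 days.

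The G2/M list had a median log2 ratio of 0.91 with 12 of 40 higher and none lower, among them cyclin B1, CCNB1 (2.53-fold), the spindle checkpoint kinase BUB1 (2.44-fold), KIF23 (2.38-fold) and CENPF (2.37-fold). The G1/S list had a median of 0.47 with 0 of 39 past 2-fold. Metallothioneins (0.44), glycolysis (0.29), ribosome biogenesis (0.22), oxidative phosphorylation (0.16), adhesion (0.16, 2 of 32 higher, CD82 at 2.81-fold) and the cytoskeleton (0.12) were above random lists too, the last 6 with none lower. Interferon-stimulated genes had a median of -0.63 with 9 of 35 lower, such as MX1 (2.68-fold) and IFITM1 (2.47-fold) besides IFIT2 and IFI27. MHC class II genes had a median of -0.79 with 4 of 12 lower, HLA-DRA, HLA-DPA1 (log2 ratio -1.32), HLA-DMB (2.24-fold) and CD74 (2.02-fold). Complement genes (-0.42, 3 of 19 lower, SERPING1 at 2.61-fold), monocyte markers (-0.31, 2 of 15 lower), cytokines and chemokines (-0.29, 7 of 30 lower and 1 higher, CXCL11 at 2.77-fold) and M2 genes (-0.30, 2 of 23 lower, 1 higher) were below random lists as well. Poly-A control scaling, which moved the median of all genes from 0.04 to 0.30, took these medians to -0.13 (complement), -0.02 (monocyte), -0.01 (cytokines and chemokines) and -0.02 (M2). The lists that follow were also below random lists. The sign of their medians turned under poly-A control scaling, by that shift of all genes, which says nothing of their place among other genes: Fc and pattern receptors (-0.27, 4 of 36 lower, 1 higher), unfolded protein response (-0.19), macrophage markers (-0.16, 2 of 26 lower, 1 higher), chemokine and cytokine receptors (-0.11, 1 of 35 lower), MHC class I (-0.11) and lysosomal genes (-0.10, 1 of 45 lower).

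The other lists had medians inside the random range in this comparison. These were progenitor and granule genes (0.19, 1 of 16 higher), cell cycle inhibitors (-0.09, 1 of 14 lower), NF-kB targets (-0.09), lipid handling (0.00, 2 of 36 higher and 1 lower), cholesterol synthesis (0.05), matrix (0.06, 4 of 35 higher and 2 lower), immediate early genes (0.07), myeloid transcription factors (0.04, 2 of 33 higher and 1 lower), protein kinase C and phorbol receptors (0.02, 1 of 21 lower), NADPH oxidase (-0.02), antioxidant and iron (0.06), eicosanoid (0.08, 1 of 20 lower), hypoxia (0.11), apoptosis (0.01, 1 of 25 lower), p53 targets (0.03, 1 of 18 higher) and M1 genes (-0.10, 3 of 21 lower), and the dendritic (-0.01), granulocyte (0.05), osteoclast (-0.03), lymphoid (0.03), erythroid and megakaryocyte (0.20) and fibroblast, epithelial and endothelial markers (0.15). Within them MMP7 (2.92-fold), TGM2 (2.34-fold) and the osteoclast fusion gene DCSTAMP (2.72-fold) were higher, and PLA2G7 (2.25-fold) was lower.

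**Figure D4:**
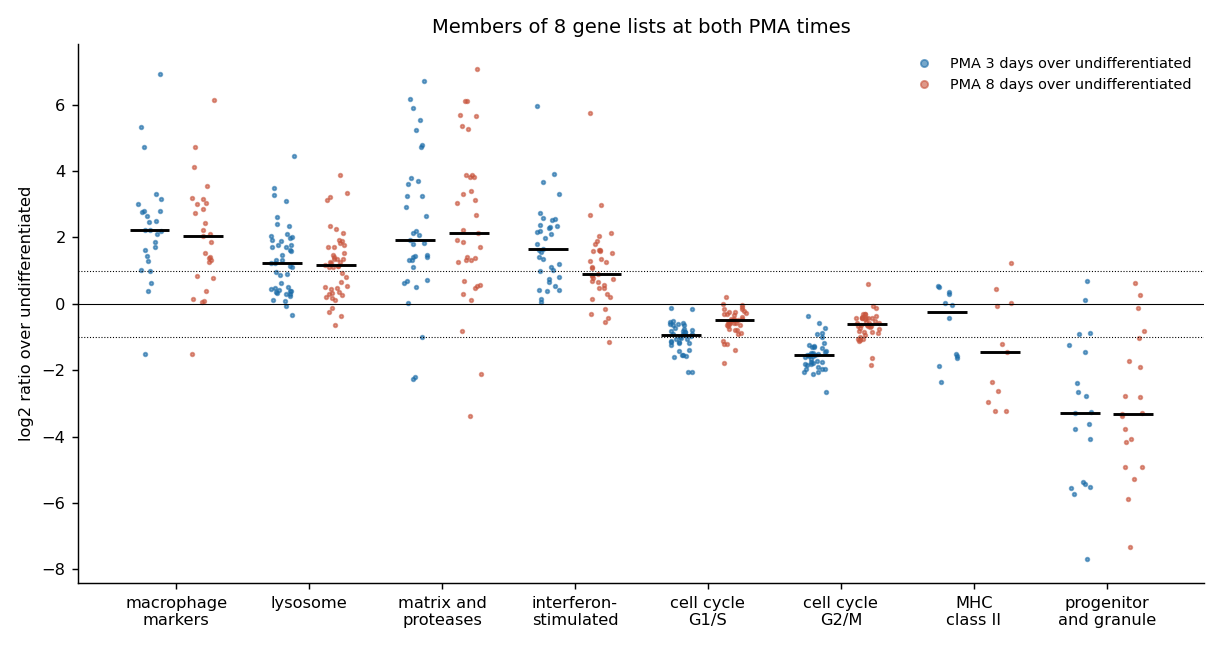
Log2 ratio over undifferentiated cells of each measured member of 8 gene lists at PMA 3 days (blue) and PMA 8 days (red), 1 point per gene; black bars are medians and dotted lines mark 2-fold. The G2/M median lies at -1.54 and -0.60 and the interferon median at 1.64 and 0.91, while the progenitor and granule median lies at -3.29 and -3.31.

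Some genes lay nearer the undifferentiated level again on the PMA 8 days array. Of the genes higher at PMA 3 days, 70 were at least 2-fold lower again at PMA 8 days, and of the genes lower at PMA 3 days, 88 were at least 2-fold higher again. A simulation added after the data were seen, of PMA arrays that differ by the technical spread alone, gave at most 6 and 4 such genes. These counts may be too low for genes dim on the PMA arrays alone, whose spread was set by the mean over all 3 arrays. Both ratios use the PMA 3 days array, and an error of that culture or its labelling would also give such genes. ADGRE1 went from 1309 signal units to 6182 and back to 1384, GGTA1 from 255 to 1092 to 292, THBS1 from 1111 to 4891 to 1548 and C1QC from 369 to 2289 to 756; CCL8 went from below the floor to 647 and back to 201. In the other direction CENPM went from 1926 to 447 and back to 1449, ATAD3B from 1867 to 334 to 1104, SLC6A8 from 4001 to 486 to 1454, and LRP3 and BICDL1 passed below the floor at PMA 3 days; the second-brightest probe set of BICDL1 went the other way between the PMA arrays (log2 ratio -0.32). A further 2-fold increase from PMA 3 to 8 days was seen in 21 genes higher at both times, and a further decrease in 10 genes lower at both.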

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

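No tests in this part were chosen after the results were seen, because none was run. Signal in probe sets that carry no single gene name was not covered by the gene counts of the report. Of 13522 such probe sets, 5403 entered the comparison of PMA 3 days with undifferentiated cells by the floor rule, and 5545 that of PMA 8 days. Among the 5403, 274 were at least 2-fold higher and 665 lower at PMA 3 days. Among the 5545, 239 were higher and 729 lower at PMA 8 days. By at least 4-fold, 66 and 47 were higher and 82 and 97 lower. Between the PMA arrays 49 of 4884 were higher and 50 lower at PMA 8 days, 0 of them by 4-fold. These probe sets match several genes or none in the platform table. No explanation was tested.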

How the results depend on the processing

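All alternatives here were chosen before the data were examined except poly-A control scaling, which was chosen after the controls were seen. Each result was computed again under other scalings (quantile normalization, centring, poly-A controls), floors (40th and 60th percentile, a pseudocount, only genes above the floor), probe sets (median, second-brightest, without those ending in _x_at, all going the same way) and thresholds. Counting each list median under each alternative, 965 kept their direction and size, 266 moved and 13 turned round, some of these for the same list; counted likewise, 2954 named gene ratios stayed, 643 moved and 13 turned round, some for the same gene. Leaving out a replicate was not possible with 1 array per condition.

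Counts followed the threshold by construction. At 1.5-fold 2369 genes were higher and 3168 lower at PMA 3 days over undifferentiated, 2380 and 2718 at PMA 8 days over undifferentiated, and 938 and 617 at PMA 8 days over PMA 3 days; 4077 went the same way at both times. At 4-fold these were 504 and 275, 446 and 234, 2 and 1, and 568. The second-brightest probe set exists for fewer genes, and gave 633 and 650, 606 and 567, 88 and 55, and 882.

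Poly-A control scaling gave 2455 genes lower at PMA 3 days over undifferentiated, and 510 higher and 43 lower at PMA 8 days over PMA 3 days, since it shifts all ratios of an array together. The comparison of the PMA arrays also followed the floor: 377 were higher and 188 lower with the 40th percentile, 97 were higher with the 60th, and a pseudocount gave 105 and 67; the cause was not tested. The correlation of the ratios at both times was 0.918 and 0.9393 with the lower and higher floor, 0.9235 with the median of probe sets and 0.9113 with the second-brightest; the cause was not tested.

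Under poly-A control scaling, by its shift of all genes alike, which does not bear on a list's place among other genes, list medians at PMA 8 days over PMA 3 days turned to 0.1302 (macrophage), 0.1861 (lysosome), 0.1802 (MHC class I), 0.0197 (Fc and pattern receptors), 0.0328 (unfolded protein response) and 0.1752 (chemokine and cytokine receptors), and at PMA 3 days over undifferentiated to -0.1142 (cytoskeleton) and -0.0525 (apoptosis). With the second-brightest probe set they turned to -0.087 (Fc and pattern receptors) and -0.2705 (p53 targets) at PMA 8 days, and for chemokine and cytokine receptors to -0.5871 at PMA 3 days and -0.4235 at PMA 8 days, all over undifferentiated. In that order these were over 17, 7, 19 and 18 genes, fewer than in the main medians. The chemokine and cytokine receptor median at PMA 8 days was -0.0655 over genes above the floor only. The cause was not tested.

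Some genes turned round with the second-brightest probe set. At PMA 3 days over undifferentiated these were PRKCA (0.0244), RAP1A (-0.7536), BCL2 (0.1141) and COL1A1 (-0.3905). At PMA 8 days over undifferentiated they were CDC25C (0.2496), RAP1A (-0.7223), P4HA2 (-0.1202), BCL2 (0.0801) and COL1A1 (-0.0849), and at PMA 8 days over PMA 3 days BICDL1 (-0.3242) and ITGA7 (-0.0267). COL1A1 also turned with the median of probe sets, to -0.029 and -0.0849. The cause was not tested.

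The technical spread was widest for dim genes: the technical SD of a log2 ratio between the PMA arrays was 0.329 for dim, 0.226 for middle and 0.144 for bright genes.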

Other observations

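The tests of explanations in this part were chosen after the results were seen, as were poly-A control scaling, the gene families, which were formed from shared symbol stems, and the genes named from them; the second-brightest probe sets, the other scalings and the simulated unchanged arrays they draw on were planned. Zinc finger genes named ZNF, many of them transcription factors, had medians below random lists at both PMA times. Of 402 measured, 40 were lower and 8 higher at PMA 3 days (median log2 ratio -0.37) and 48 lower and 7 higher at PMA 8 days (-0.40). Of all genes 10.7% and 8.39% were lower and 10.3% and 9.72% higher, so that few higher calls set the family apart more than many lower ones. ZNF670 went from 2806 signal units to 611 and 721. Nuclear pore genes (NUP) had medians of -0.50 and -0.35, with only 2 and 1 of 23 lower by 2-fold.

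Tetraspanins, membrane proteins that organise receptors and adhesion molecules, had medians above random lists. At PMA 3 days 7 of 17 TSPAN genes were higher and 1 lower (median 0.73), and at PMA 8 days 7 of 19 were higher and none lower (0.82). TSPAN4 went from 572 to 1587 and 1551. Sorting nexins (SNX), which sort endosomal cargo, had medians of 0.35 and 0.32, with 4 of 28 and 4 of 29 higher and 0 and 1 lower. Of all genes 10.3% and 9.72% were higher, so the number of higher SNX genes was near the share of all genes. SNX9, the largest, went from 1631 to 7465 and 6872. Of 84 families 10 were above and 6 below random lists at PMA 3 days over undifferentiated. At PMA 8 days over undifferentiated these were 15 and 9, and at PMA 8 days over PMA 3 days 7 and 5. About 4.2 per comparison, in both directions together, would fall outside by chance if members of a family varied like genes drawn at random. Whether they do was not tested, so 4.2 may be too low.

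Control transcripts were read as values only. The poly-A controls, added before labelling, had a median log2 ratio of 0.31 (PMA 3 days over undifferentiated), 0.02 (PMA 8 days over undifferentiated) and -0.29 (PMA 8 days over PMA 3 days) over 24 probe sets. The hybridisation controls had -0.10, -0.09 and -0.02 over 18.

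G2/M genes were nearer the undifferentiated level at PMA 8 days than at PMA 3 days. Leftover undifferentiated cells could give this, but then progenitor and granule genes would come back alike, and the 16 of them that were 2-fold lower at PMA 3 days regained a median of 1.37% of the difference (quartiles 0.0604 to 5.21) against 43.7% (35.8 to 54.5) for the 34 such G2/M genes, both chosen on the array the regain starts from. Noise of the chosen probe sets would leave the second-brightest near 0, and over 17 members their median was 0.84. Scaling as the whole cause would let the list median of 0.91 go to 0 under another scaling, and its value nearest to 0 over those tried was 0.88. The median of all genes ran only from 0.01 to 0.30 under these scalings. Shifts of this size could not bring 0.91 to 0, so the value of 0.88 cannot decide this. Under quantile normalization, which does not move all genes alike, the list median less that of all genes was 0.88. Longer time in culture, longer PMA, longer time without it and differences between cultures were not tested and stay open.

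The interferon-stimulated list had a median below 0 at PMA 8 days over PMA 3 days. The second-brightest probe sets of 17 members had a median of -0.82, which noise of the chosen probe sets would not give. The list median of -0.63 was -0.35 at its nearest to 0, under poly-A control scaling, which moves all genes alike (their median from 0.04 to 0.30). Under quantile normalization, which does not, the list median less that of all genes was -0.62, against -0.67 as deposited. With 1 culture per condition, a difference between cultures remains possible, as do time and PMA exposure.

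The genes 2-fold apart between the PMA arrays were more than the simulated technical spread gave. Among middle and bright genes there were 85 calls, against at most 1 on simulated unchanged arrays. For dim genes the direction of the second informative probe set was taken from the median log2 ratio of such probe sets, 0.087. It went the same way as the call in 77.8% (49 of 63, exact 95% interval 65.5 to 87.3), where noise alone would give about 50%. Probe sets of a gene may share probes, which would raise this share. Whether the genes differ between cultures of the same kind could not be tested.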
